A study of Arabidopsis thaliana with 6 samples.

How the data were processed

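The study measured mRNA by paired-end Illumina sequencing of total RNA from 25-day-old Arabidopsis seedlings, 3 samples of wild type and 3 of EsANAC029-OE. Whether the 3 replicates of a group came from separate plantings or from pooled plants is not stated in the labels, and no batch or date is given. Per the submitters' processing notes, CASAVA 1.8, HISAT2 and edgeR were used with the TAIR10 genome; the step each tool served, the read counter, the strand setting and the annotation release are not given in the sources used here. The deposited values are FPKM, fragments scaled to gene length and to an effective library size, and gene length is given in bases (unit: other) beside them in the deposited table. The table's header names no unit, and FPKM was inferred from the values. Each value multiplied by its gene length was a whole multiple of 1 step per library, for 100% of values within a tolerance of 1e-06, so the reads behind each value could be recovered. The recovered reads sum to 19608819 to 21715274 per library. The scale that the authors applied beyond the library total, 0.9198, 0.8834 and 0.8716 for wild type and 1.059, 1.252 and 1.149 for EsANAC029-OE, equals median-of-ratios (RLE) factors computed from the recovered reads.

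Samples were grouped by the genotype in the labels, and each column was joined to its sample by genotype, age and replicate number. The design, the gene lists, the rule for named genes and the alternatives were written before the data were examined. That design named a count model for raw counts and, for a file of normalized values, limma-trend. As the table holds FPKM, limma-trend was used. Values were transformed as log2(FPKM + 1), genes at 1 FPKM or more in at least 3 libraries were kept (17221 of 32962), and genotype was fitted with limma 3.58.1 in R 4.3.3, with a trended, moderated variance and two-sided tests. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are on this scale with a pseudocount of 1, so they understate changes of genes with low values. A group mean is given as mean ± SD with n = 3.

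The named genes are the 8 largest rises and the 8 largest falls among called genes whose groups do not overlap, which have a symbol and a mean log2(CPM + 1) of at least 1, up to 3 called members with the smallest p of each list described, and 9 genes fixed whatever their values (NAC029, HY5, PHYA, PHYB, CRY1, GPRI1, GLK2, FT and FLC). Others are said to have been chosen after their values were seen. The 36 gene lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 33 lists with at least 5 tested members. One list member was dropped because its locus carries another gene's name. Each list was also tested with a correlation estimated from its genes and with fry. Some genes stand in more than 1 list, such as SAG101 and ZAT12. Terms came from the notes of the RefSeq annotation of the same assembly, where 32548 of 32962 loci matched and 32532 had identical coordinates. Terms with 10 to 500 tested genes were used, and 317 genes whose note gives only a number of processes carry no term. Shares of reads and marker sums were compared with two-sided exact permutation tests.

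The alternatives were RLE and upper-quartile factors, library size alone, other filters on low values, a replicate block, no organelle genes, limma-voom on the recovered reads, a pseudocount of 0.1 with no filter, stricter thresholds and leaving out each library in turn. Trimmed-mean scaling and library weights were added after the data were seen. The test was tried on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. With the spread of the wild-type libraries it called 43.5% of the 92 tested 2-fold and 82.3% of the 96 tested 4-fold changes (12 false calls of 131), and with the spread of both groups 1.05% of 95 and 37.5% of 96 (1 false call of 38). The other changed genes did not pass the filter. Protein families given among the other observations are the Pfam names in the table's gene descriptions, and the table's column of transcription factor families was not used.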

Results

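Messenger RNA was sequenced from Arabidopsis seedlings at 25 days of age, grown with 16 h of light and 8 h of dark at 25 °C. The 6 libraries fall into 2 groups, with 3 libraries of wild type (Col-0) and 3 of EsANAC029-OE, a line that overexpresses EsANAC029, a NAC transcription factor of the grass Elymus sibiricus. The wild-type libraries held 21715274, 21121138 and 21154883 reads in genes, and the overexpressor libraries 21688167, 20802908 and 19608819. A count of 3 reads, taken as the floor, corresponds to 0.138 to 0.153 CPM (reads scaled to the library total), and such floors cover counting error only. The table lists 32962 genes, of which 129 are unnamed loci, and 17221 genes were tested. The series title places the work in the response to light, so the single comparison asks which transcripts differ between the overexpressor and wild type under ordinary growth light. The transcript of EsANAC029 itself was not analysed here, because the values cover Arabidopsis genes.

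Genes that rose in EsANAC029-OE included 21 of 31 tested genes of salicylic acid defence, 6 of 22 of senescence and 7 of 35 NAC transcription factors. Genes that fell included 8 of 20 of the light-harvesting antenna, 4 of 31 of the photosystems, 3 of 21 of chlorophyll synthesis, 8 of 46 of light signalling, 5 of 26 of auxin response, where 1 rose, and 5 of 15 of cold response, where 2 rose. Each of these 9 lists was called by limma's camera with a preset correlation, and none with a correlation estimated for each list (adjusted p = 0.555 to 0.599). In all, 1359 of 17221 genes were called at a Benjamini-Hochberg adjusted p under 0.05 by limma, and of these 743 rose and 616 fell. A change of at least 2-fold was seen for 1150 of them, with 643 risen and 507 fallen. Over all 17221 tested genes 4878 had an unadjusted p under 0.05 by limma. Counts of list members adjusted over a list alone, or unadjusted, stand against that background. In each of the 1359 called genes the 3 values of one group lay on the same side of all 3 values of the other. Of all tested genes 6875 did so, or 39.9%, where chance gives 10%. The median log2 fold change over tested genes was −0.00914. Scaling by library size alone moved this median to 0.311 and gave 2749 risen and 377 fallen genes, so the balance of risen to fallen genes depends on the scaling. EsANAC029-OE replicate 1 stood apart from the other overexpressor libraries, with correlations over tested genes of 0.691 to 0.734 with the wild-type libraries against 0.857 to 0.899 for replicates 2 and 3. Without it 2748 genes were called, 1151 risen and 1597 fallen, and 1169 of these were among the 1359. Leaving out 1 of the other libraries gave 59 genes (without wild type replicate 3) to 924 genes (without EsANAC029-OE replicate 3).

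Genes of the salicylic acid pathway had the highest median rise of the lists fixed before the data were examined. Of 31 tested members 21 rose and none fell, and 27 rose adjusted over the list alone. PR1, an extracellular pathogenesis-related protein and the usual marker of salicylic acid signalling (AT2G14610, TAIR10 chromosome 2, 6241640 to 6242541), was at 1.16 ± 1.88 FPKM in wild type and 2103 ± 884 FPKM in EsANAC029-OE (mean ± SD, n = 3 each). Its log2 fold change was 10.18 (SE 0.614, limma adjusted p = 0.00454). BGL2, the beta-1,3-glucanase also called PR2 (AT3G57260, chromosome 3, 21188397 to 21189967), rose from 19.7 ± 11.4 to 1612 ± 1668 FPKM, a log2 fold change of 5.96 (SE 0.817, adjusted p = 0.0171). EsANAC029-OE replicate 1 carried much of that mean, with 3531 FPKM against 507 and 799 FPKM in replicates 2 and 3. AIG1, a GTP-binding protein induced by bacterial avirulence signals (AT1G33960), rose from 0.481 ± 0.398 to 166 ± 35.8 FPKM, with the smallest adjusted p of the named genes (0.00203). UGT76B1, a glucosyltransferase that acts on salicylic acid (AT3G11340), rose from 0.154 ± 0.0663 to 9.67 ± 2.59 FPKM. EDS16, the isochorismate synthase of salicylic acid production, rose by 3.98 on the log2 scale, and PAD4 and EDS1, its regulators, by 2.28 and 2.09. These last 3 were chosen from the list after their values were seen. Other large rises were those of DLO1, a 2-oxoglutarate-dependent oxygenase that hydroxylates salicylic acid (log2 fold change 6.97), ARD, an acireductone dioxygenase (6.47), CHI, a chitinase (5.94), and CML41, a calmodulin-like protein (5.52). The median log2 fold change of the list was 3.16 (camera adjusted p = 8.72e-19), and with a correlation estimated for each list the adjusted p was 0.555. Against the wild-type mean the list's median was 3.86 in EsANAC029-OE replicate 1, 2.52 in replicate 2 and 2.41 in replicate 3. Without replicate 1, 16 members rose. Members under 1 FPKM in every wild-type library, such as AIG1, UGT76B1 and WRKY38, fell below the filter there and were not tested.

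In the list of senescence and chlorophyll breakdown 6 of 22 tested members rose and none fell, and adjusted over the list alone 12 rose and 2 fell. SAG13, a short-chain dehydrogenase and early senescence marker (AT2G29350, chromosome 2, 12600914 to 12602556), went from 1.57 ± 0.729 to 255 ± 248 FPKM (log2 fold change 6.22, SE 0.69, adjusted p = 0.0105). Its values were 538, 150 and 78.4 FPKM in EsANAC029-OE replicates 1, 2 and 3. SAG21, a mitochondrial protein of the late embryogenesis abundant family, rose by 2.84 on the log2 scale, and SAG101, a lipase-like partner of EDS1 that the salicylic acid list also holds, rose by 1.82. The list's median was 1.8 (camera adjusted p = 8.26e-05, and adjusted p = 0.599 with an estimated correlation). Its median was 3.07 in replicate 1, 1.52 in replicate 2 and 0.747 in replicate 3. SAG12, a cysteine protease of late senescence, was listed at 0 in the 3 wild-type libraries and at 230, 132 and 0 FPKM in EsANAC029-OE replicates 1, 2 and 3. It was singled out after its values were seen, and it was not tested, because it reached 1 FPKM in fewer than 3 libraries. Of 35 tested NAC transcription factors 7 rose and none fell, and 10 rose adjusted over the list alone; without EsANAC029-OE replicate 1 there were 4. Among them anac061 rose by 2.93, anac016 by 2.59 and NAC100 by 2.24 on the log2 scale, with adjusted p of 0.0162, 0.0281 and 0.02. The values of anac016 and NAC100 are low, and neither was called without any 1 wild-type library or tested without any 1 overexpressor library, where both fell below the filter. ANAC087 and JUB1, which also rose, likewise fell below the filter without EsANAC029-OE replicate 1. The median of the NAC list was 0.82 (camera adjusted p = 2.21e-06, and adjusted p = 0.555 with an estimated correlation), and it was 1.97, 0.997 and 0.45 in replicates 1, 2 and 3. NAC029, the Arabidopsis gene also called NAP, which promotes leaf senescence (AT1G69490, chromosome 1, 26122080 to 26123514), was at 2.28, 2.4 and 3.90 FPKM in wild type and at 88.6, 21.5 and 5.35 FPKM in EsANAC029-OE. It lay above wild type in all 3 overexpressor libraries and did not pass the test (log2 fold change 2.62, SE 0.9, adjusted p = 0.123). Reads of the EsANAC029 transgene that align to this locus would add to its values, and the table cannot tell them apart.

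**Figure D1:**
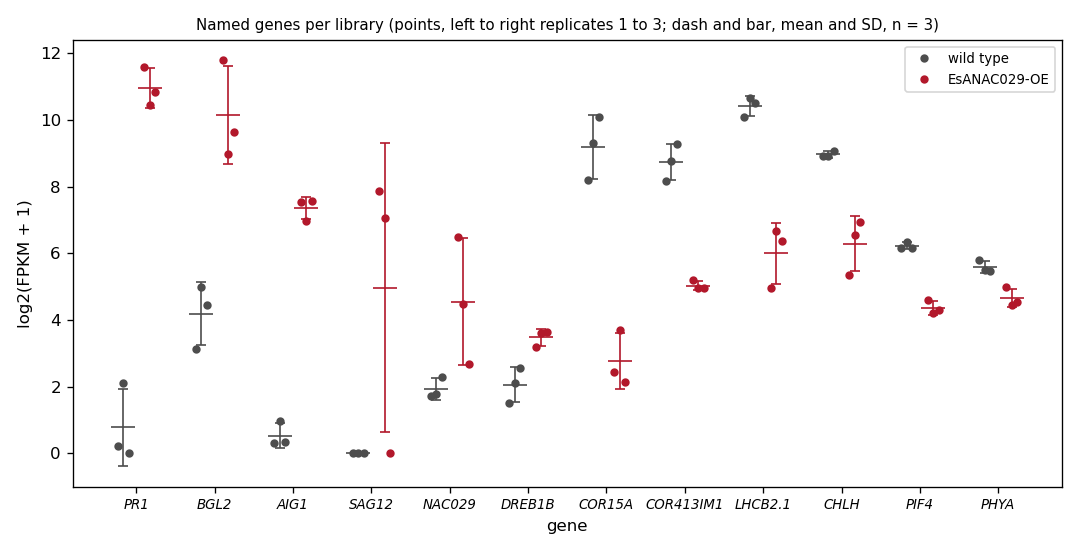
Values of 12 genes in the 6 libraries, as log2(FPKM + 1), with 1 point per library and the mean and SD (n = 3) of wild type in grey and EsANAC029-OE in red. PR1 averaged 1.16 FPKM in wild type and 2103 FPKM in EsANAC029-OE, COR15A averaged 671 and 6.66 FPKM, and SAG12 was at 0 in EsANAC029-OE replicate 3.

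Of 20 tested genes of the light-harvesting antenna 8 fell and none rose, and 17 fell adjusted over the list alone. LHCB2.1, an antenna protein of photosystem II (AT2G05100, chromosome 2, 1822990 to 1824480), fell from 1386 ± 273 to 70.7 ± 36.4 FPKM (log2 fold change −4.42, SE 0.483, adjusted p = 0.0101). LHCB2.2 and LHCB2.4 had log2 fold changes of −3.70 and −4.84; these copies are nearly identical, so the share of reads given to each is uncertain. LHCB7, a rarer antenna gene, fell from 11.8 ± 2.28 to 4.49 ± 0.28 FPKM. The antenna list had a median log2 fold change of −2.50 (camera adjusted p = 1.64e-10, and adjusted p = 0.555 with an estimated correlation). Of 31 nuclear genes for photosystem and electron transport subunits 4 fell and none rose, and all 31 fell adjusted over the list alone. All 31 had an unadjusted p under 0.05 by limma, so that adjustment could remove none of them. The correlation estimated among these genes was 0.981, and among antenna genes 0.891, so their members are far from separate measurements. PSAD2, PSAH1 and PSAD1, subunits of photosystem I, had log2 fold changes of −2.46, −1.94 and −2.09. The median of that list was −2.09 (camera adjusted p = 1.03e-12, and adjusted p = 0.555 with an estimated correlation). Chlorophyll synthesis held 3 fallen genes of 21, or 5 adjusted over the list alone. They were CHLH, the large subunit of magnesium chelatase (AT5G13630, 499 ± 35.3 to 84.8 ± 41.5 FPKM, log2 fold change −2.68), HEMA1, the glutamyl-tRNA reductase that starts the pathway (−1.59), and CAO, which makes chlorophyll b (−0.998). Its median was −1.29 (camera adjusted p = 5.43e-06, and adjusted p = 0.599 with an estimated correlation). No member of the Calvin-Benson cycle was called by limma among 18 tested, over all genes or adjusted over the list alone, nor by limma-voom. In that list 13 members had an unadjusted p under 0.05, all lower, and the median was −1.64 (camera adjusted p = 6.06e-06, and adjusted p = 0.599 with an estimated correlation). The correlation estimated among its genes was 0.966.

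Of 78 tested genes encoded in the plastid 15 fell and none rose, and 35 fell adjusted over the list alone; without EsANAC029-OE replicate 1 there were 23. Their median log2 fold change was −1.23 (camera adjusted p = 4.69e-16, and adjusted p = 0.555 with an estimated correlation). PSBN, a small protein used in photosystem II assembly, fell from 8.59 ± 1.47 to 0.985 ± 0.601 FPKM, and ATPB, the beta subunit of the plastid ATP synthase, fell from 58.5 ± 3.48 to 16.0 ± 6.19 FPKM. Plastid-encoded genes took 0.0494 ± 0.000417% of reads in wild type and 0.0235 ± 0.0102% in EsANAC029-OE (n = 3 each, exact permutation p = 0.1, two-sided). Mitochondrion-encoded genes took 0.00368 ± 0.000539% and 0.00692 ± 0.00439% (exact permutation p = 0.2). Whether reads at such small shares follow the total level of plastid or mitochondrial transcripts was not tested, so these falls and rises may not measure it. The 20 most abundant genes of each library, led in wild type by antenna and Rubisco genes, took 14.6 ± 0.451% and 7.06 ± 1.12% of reads (exact permutation p = 0.1). With 3 libraries against 3 an exact p cannot go below 0.1, so none of these 3 shares could pass 0.05. The fall of the nuclear photosynthesis lists was deepest in EsANAC029-OE replicate 1. The medians of the antenna list were −3.37, −2.27 and −1.72 in replicates 1, 2 and 3, those of the photosystem list −3.15, −1.83 and −1.23, those of chlorophyll synthesis −2.59, −0.733 and −0.44, and those of the Calvin-Benson cycle −2.89, −1.45 and −0.667. Without replicate 1, 17 antenna genes, 30 photosystem genes, 7 chlorophyll synthesis genes and 9 Calvin-Benson genes fell.

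**Figure D2:**
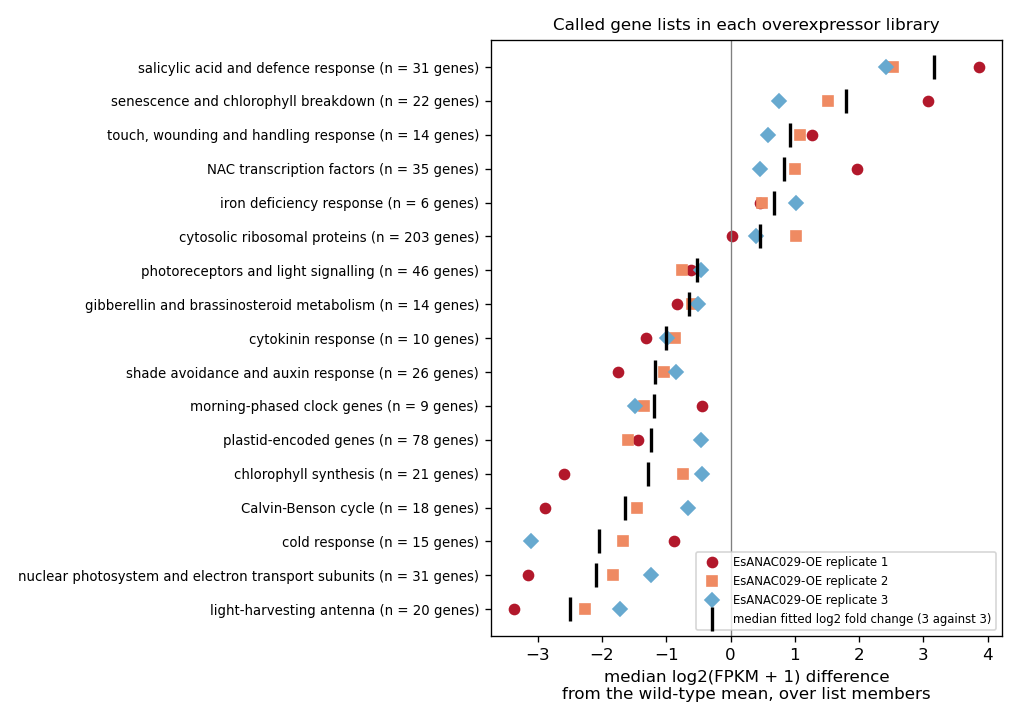
Median log2(FPKM + 1) difference from the wild-type mean over the tested members of each of the 17 called lists, with 1 symbol per EsANAC029-OE library and a black bar for the median fitted log2 fold change. The salicylic acid list had medians of 3.86, 2.52 and 2.41 and the antenna list −3.37, −2.27 and −1.72 in replicates 1, 2 and 3, while cytosolic ribosomal proteins were at 0.0144 in replicate 1.

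Of 46 tested photoreceptor and light signalling genes 8 fell and none rose, and 13 fell adjusted over the list alone, with a median log2 fold change of −0.53 (camera adjusted p = 2.21e-06, and adjusted p = 0.555 with an estimated correlation). PIF4, a bHLH factor that phytochrome removes in light and that drives elongation (AT2G43010, chromosome 2, 17886101 to 17889087), fell from 74.1 ± 5.58 to 19.7 ± 2.95 FPKM (log2 fold change −1.87, SE 0.169, adjusted p = 0.00605). BBX24, a B-box factor, had a log2 fold change of −1.60, and HFR1, an atypical bHLH factor that binds PIF proteins, one of −1.69. PHYA, the phytochrome of far-red light (AT1G09570), fell from 47.3 ± 5.94 to 24.5 ± 5.2 FPKM (adjusted p = 0.0451). PHYB was at 27.2 ± 4.59 and 16.1 ± 1.28 FPKM (adjusted p = 0.0606), CRY1 at 84.5 ± 8.33 and 56.5 ± 21.2 FPKM (adjusted p = 0.224), GPRI1, also called GLK1, at 80.1 ± 19.5 and 61.9 ± 11.4 FPKM (adjusted p = 0.407), and GLK2 at 30.7 ± 8.57 and 13.6 ± 3.25 FPKM (adjusted p = 0.0568), and none of these 4 passed the test. HY5, a bZIP factor central to growth in light (AT5G11260), was at 1.56 ± 0.315 and 1.95 ± 0.753 FPKM, a difference within the spread of the libraries (adjusted p = 0.655). Without EsANAC029-OE replicate 1, 15 genes of this list fell.

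In shade avoidance and auxin response 5 of 26 tested genes fell and 1 rose, and adjusted over the list alone 18 fell and 2 rose. SHY2, the auxin response repressor IAA3 (AT1G04240), fell from 38.8 ± 10.6 to 3.93 ± 2.02 FPKM (log2 fold change −3.08, SE 0.399, adjusted p = 0.0155), and SAUR21, one of a set of near-identical copies, had a log2 fold change of −2.48. GH3.5, an enzyme that conjugates auxin and also salicylic acid to amino acids, rose by 2.14 on the log2 scale. The list's median was −1.17 (camera adjusted p = 1.55e-05, and adjusted p = 0.555 with an estimated correlation). In gibberellin and brassinosteroid metabolism 3 of 14 genes fell and none rose, or 4 adjusted over the list alone. They were GA3OX1, the last step to active gibberellin (−1.64), and the brassinosteroid synthesis genes CYP90B1, also called DWF4 (−1.76), and CYP90A1, also called CPD (−2.03). The median of that list was −0.65 (camera adjusted p = 0.0324, and adjusted p = 0.555 with an estimated correlation). Most fits with 1 library left out lost this call. In cytokinin response 1 of 10 genes fell, the response regulator ARR6 (−2.00), and 4 fell adjusted over the list alone, with a median of −1.01 (camera adjusted p = 0.0304, and adjusted p = 0.555 with an estimated correlation). Without EsANAC029-OE replicate 1, 11 genes of shade and auxin response, 5 of gibberellin and brassinosteroid metabolism, 2 of cytokinin response and 7 of the morning clock fell. Of 9 morning-phased clock genes 3 fell and none rose, or 5 adjusted over the list alone. AT3G54500, known as LNK2, had a log2 fold change of −1.94, RVE7 one of −1.69 and CCA1 one of −1.20. Their median was −1.20 (camera adjusted p = 0.0017, and adjusted p = 0.555 with an estimated correlation). Of 14 evening-phased clock genes 2 fell, PCL1, known as LUX (−1.28), and APRR5 (−0.86), and that list was not called (median −0.35, camera adjusted p = 0.0645); without EsANAC029-OE replicate 1, 4 of them fell.

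Cold-regulated genes included some of the largest falls. Of 15 tested members of the cold list 5 fell and 2 rose, and adjusted over the list alone 6 fell and 2 rose. COR15A, a chloroplast protein that protects membranes in freezing (AT2G42540, chromosome 2, 17710441 to 17712330), fell from 671 ± 400 to 6.66 ± 4.74 FPKM (log2 fold change −6.43, SE 0.599, adjusted p = 0.00659), the largest fall of the named genes. Its neighbour COR15B fell from 240 ± 80.0 to 23.3 ± 7.64 FPKM; the copies are alike, so the share of reads given to each is uncertain, and their summed values are given among the other observations. COR413IM1, a protein of the chloroplast inner membrane (AT1G29395), fell from 447 ± 163 to 31.7 ± 3.16 FPKM (log2 fold change −3.71, adjusted p = 0.00509). The 2 that rose were ZAT12, a zinc finger factor of stress responses (log2 fold change 3.06), and DREB1B, the cold-response activator CBF1 (3.34 ± 1.5 to 10.3 ± 1.9 FPKM, log2 fold change 1.43, adjusted p = 0.043). DREB1C and DREB1A, its neighbours CBF2 and CBF3, were at 4.54 ± 3.86 and 1.55 ± 0.455 FPKM in wild type and at 10.5 ± 2.06 and 1.42 ± 0.588 FPKM in EsANAC029-OE, and neither passed the test (adjusted p = 0.202 and 0.855). The 3 DREB1 genes were singled out after their values were seen. The list's median was −2.05, with an SD over members of 2.47 (camera adjusted p = 0.00573, and adjusted p = 0.599 with an estimated correlation). Its medians in EsANAC029-OE replicates 1, 2 and 3 were −0.881, −1.68 and −3.1. Wild-type libraries differed too, with COR15A at 289, 636 and 1087 FPKM in wild type replicates 1, 2 and 3. Of the list's members only AT4G33980 was not lowest in replicate 1 among wild-type libraries. RD29A and COR47, not called, were at 35.1 and 191 FPKM there, against 35.7 and 221 FPKM in EsANAC029-OE replicate 1. What varied among the wild-type plants was not tested.

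Cytosolic ribosomal proteins were slightly higher as a list, with a median log2 fold change of 0.46 over 203 tested genes (camera adjusted p = 1.64e-10, and adjusted p = 0.697 with an estimated correlation). Only 5 of them rose and 2 fell, or 3 and 1 adjusted over the list alone, and without EsANAC029-OE replicate 1 there were 32 risen and 2 fallen. RPL31A, a protein of the large ribosomal subunit, rose from 40.8 ± 5.22 to 90.2 ± 7.43 FPKM. Touch, wounding and handling genes had a median of 0.92 (camera adjusted p = 0.0324, and adjusted p = 0.717 with an estimated correlation), and 2 of 14 rose, ZAT12 and CAF1-11, a deadenylase (log2 fold change 2.52), as also adjusted over the list alone. Of 6 tested iron deficiency genes none was called by limma or by limma-voom, 1 rose adjusted over the list alone and 3 had an unadjusted p under 0.05, with a median of 0.67 (camera adjusted p = 0.0322, and adjusted p = 0.555 with an estimated correlation). In all, 17 of 33 lists with at least 5 tested members were called, 6 up and 11 down. With an estimated correlation none of the 17 was called by camera (2 lists had an unadjusted p under 0.05), and fry, a directional test of each list by itself, called 5 lists. These were antenna (adjusted p = 0.0487), light signalling (0.0225), morning clock (0.0379) and salicylic acid (0.0214), and high light and oxidative stress (0.0379), which camera did not call.

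The other lists were not called by camera. Their adjusted p values were 0.0805 for high light and oxidative stress, 0.605 for flavonoid and anthocyanin synthesis, 0.605 for low-energy and dark-induced genes, 0.648 for flowering time, 0.58 for abscisic acid and drought, 0.168 for heat shock, 0.484 for jasmonate and 0.894 for ethylene. They were 0.432 for phosphate starvation, 0.894 for nitrate, 0.688 for aliphatic and 0.141 for indole glucosinolates, 0.648 for the secondary cell wall, 0.852 for cell division and 0.437 for mitochondrion-encoded genes. Single members of these lists were called. Of 20 tested genes of high light and oxidative stress 4 fell and 2 rose, and adjusted over the list alone 5 fell and 3 rose; without EsANAC029-OE replicate 1, 10 fell and 2 rose. ZEP, the zeaxanthin epoxidase, fell from 130 ± 13.0 to 22.3 ± 6.05 FPKM, and CAT2, a catalase, fell from 87.3 ± 3.49 to 20.4 ± 13.0 FPKM. The catalase transcript CAT3 was far more abundant, at 1216, 1288 and 1061 FPKM in wild type replicates 1, 2 and 3. Neither it nor CAT1 was called (limma adjusted p = 0.816 and 0.191). ZAT12 is 1 of the 2 that rose. ACS8, an enzyme of ethylene synthesis, had a log2 fold change of −2.26, and DREB2A, a drought and heat response factor, one of 1.54. PAP17, an acid phosphatase, rose by 3.90 on the log2 scale, but it was not called without any 1 wild-type library, nor tested without any 1 overexpressor library. Of the nitrate transport genes NRT3.1 rose by 2.23 while NPF6.3 had a log2 fold change of −1.52. FT, the mobile flowering signal, was at 0.233 ± 0.111 and 0.291 ± 0.291 FPKM, FLC, a repressor of flowering, was at 0 and 0.0125 FPKM, and neither was tested. Markers of other organs had too few tested members for a list test. Floral and anther markers summed to 19.1 ± 2.49 FPKM in wild type and 8.88 ± 0.373 FPKM in EsANAC029-OE (n = 3 each, exact permutation p = 0.1), and AGL3, also called SEP4, which leaves express too, was their only called gene (log2 fold change −1.51). Root markers summed to 10.8 ± 1.11 and 12 ± 1.94 FPKM (exact permutation p = 0.7) and seed markers to 0.418 ± 0.186 and 1.25 ± 1.16 FPKM (exact permutation p = 0.4). Only 1 of 25 root markers was tested, and those not tested summed to 0.586 to 3.35 FPKM per library. Root transcripts were thus scarce in both groups, and whether roots were part of the samples was not tested.

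Among 225 annotation terms tested in each direction, 10 were enriched by a one-sided Fisher's exact test with Benjamini-Hochberg adjustment, against 7675 tested genes that carry a term. The strongest among fallen genes was starch catabolic process, with 7 of 11 genes (adjusted p = 1.13e-05). These were GWD1 (211 ± 24.3 to 87.5 ± 26.6 FPKM) and GWD3 (122 ± 8.43 to 60.7 ± 16.4 FPKM), the kinases that phosphorylate starch, the starch phosphatase DSP4 of locus AT3G52180 (78.0 ± 8.81 to 26.0 ± 10.7 FPKM), the related LSF1 (17.9 ± 1.42 to 6.48 ± 1.61 FPKM), the plastid amylase AMY3 (162 ± 13.5 to 58.4 ± 16.6 FPKM), the debranching enzyme PU1 (29.3 ± 1.48 to 9.66 ± 2.79 FPKM) and DPE2, which handles maltose in the cytosol (62.5 ± 2 to 24.5 ± 7.06 FPKM). They were named after the term was found. QQS, an orphan gene that affects leaf starch content and 1 of the 8 largest falls, went from 57.7 ± 9.42 to 4.2 ± 1.22 FPKM (log2 fold change −3.51, adjusted p = 0.00454). The other terms among fallen genes were photosynthesis (13 of 57 genes, adjusted p = 2.27e-05), circadian rhythm (6 of 13, 0.000493), response to water deprivation (9 of 65, 0.0317) and response to osmotic stress (5 of 21, 0.037). Risen genes were enriched in defense response (22 of 198, adjusted p = 0.00266), multicellular organismal development (9 of 45, 0.00719, of which 8 are NAC genes), signal transduction (19 of 188, 0.0224), response to other organism (6 of 24, 0.0229) and metal ion transport (8 of 47, 0.0317). Of the 66 named genes that were called, 4 were called whichever library was left out, PR1, COR15A, COR413IM1 and QQS. Some of the others were not tested in each fit. AIG1, UGT76B1 and DLO1 fell below the filter without any 1 overexpressor library and were called without each wild-type library. BDG2, a fallen gene, fell below the filter without any 1 wild-type library and was called without each overexpressor library.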

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

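The count of 1359 called genes stayed within 1.5 times under RLE factors (1358, the same scale as deposited), upper-quartile factors (1423), trimmed-mean scaling (1378), a filter of 1 CPM (1323), no organelle genes (1348) and a pseudocount of 0.1 with no filter (1090, with 409 fallen). Library size alone gave 3126 genes (2749 risen, 377 fallen), no filter 819 (460 and 359), limma-voom 821 (455 and 366), and an adjusted p under 0.01 gave 117 (83 and 34). Library weights, chosen after seeing the data, gave 2973 (1421 and 1552), with a weight of 0.124 for EsANAC029-OE replicate 1. Leaving out 1 library gave 59 to 2748 genes (48 to 1151 risen, 11 to 1597 fallen). The counts were 120, 156 and 59 without wild type replicates 1, 2 and 3, and 2748, 177 and 924 without EsANAC029-OE replicates 1, 2 and 3. Each of these fits had fewer samples, and why the count fell in 5 of them and rose in 1 was not tested. A count-model test planned with DESeq2 was not run. The table holds FPKM, but the recovered reads, on which limma-voom was run, would have allowed a count model.

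The replicate block gave 16 genes (13 risen, 3 fallen), 17 lists and 0 terms (5 terms and 3881 genes had an unadjusted p under 0.05 by Fisher's exact test and limma). Same-number correlations of the residuals were −0.199, −0.0531 and −0.105, and those of the other pairs of libraries ranged from −0.318 to 0.36. The residuals of each group sum to 0, so these values cannot decide whether the replicate numbers mark a shared batch. The block takes degrees of freedom, but how much of the lower count this explains was not tested.

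Of 33 lists 17 were called, 0 with an estimated correlation, 5 by fry and 16 to 20 under the other settings. Enriched terms numbered 36 by camera and 0 to 16 with a library left out (0, 0 and 1 without wild type replicates 1, 2 and 3, and 16 and 0 without EsANAC029-OE replicates 1 and 2), against 10; the 3 omissions with 0 had 12, 9 and 8 terms at an unadjusted p under 0.05. Over the settings run for each, leaving out limma-voom for lists and the pseudocount of 0.1 for both, lists kept their direction and their side of the threshold, called or not, in 467 cases, lost the call in 47, gained it in 19 and turned in 26; named genes did so in 820, 316, 9 and 5. Of the turned cases 6 lists and 2 genes belong to library size alone, which shifts the median gene from −0.00914 to 0.311, and 5 of the 6 list medians stay below it; that of ethylene, not called, lies above. Touch genes lost their call under library size alone, library weights and without wild type replicate 1 or 3 or EsANAC029-OE replicate 2, and iron genes under library size alone and without wild type replicate 3 or EsANAC029-OE replicate 3. Gibberellin and brassinosteroid genes lost it in 5 of 6 omissions, and cytokinin genes without wild type replicate 1 or EsANAC029-OE replicate 3 and under both other filters.

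The turned values follow, none called in the 3 against 3 comparison. Library size alone gave 0.00587 for the evening clock, 0.018 for abscisic acid, 0.11 for jasmonate (called there as lower than other genes, adjusted p = 0.0202, range over its alternatives 0.0155 to 0.945), 0.34 for ethylene, 0.013 for aliphatic glucosinolates, 0.21 for cell division, 0.012 for GPRI1 and 0.13 for DREB1A. For the others the cause was not tested. Flowering (0.00084) went to −0.012 with upper-quartile factors, −0.0464 with 1 CPM, −0.0022 without organelle genes and −0.073 with library weights, which also gave 0.25 for cell division and −0.021 for mitochondrion-encoded genes. With a library left out the ranges were −0.32 to 0.047 for flowering, −0.69 to 0.12 for abscisic acid, −0.80 to 0.21 for jasmonate, −0.13 to 0.057 for ethylene, −0.014 to 0.33 for nitrate, −0.77 to 0.26 for aliphatic glucosinolates, −0.74 to 0.55 for cell division, −0.064 to 0.51 for mitochondrion-encoded genes, −0.015 to 0.31 for HY5 and −0.28 to 0.038 for DREB1A.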

Other observations

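Chosen only after the results were seen were the tests of protein families and of genes absent from 1 group, the tests of marker tissue, of a change carried further, of scaling, of time of day and of the cold genes, and the 2 narrower counts of neighbours. Among 234 protein families per direction, fallen genes were enriched in chlorophyll a-b binding proteins (8 of 20 genes, Benjamini-Hochberg adjusted p = 8.49e-05 by Fisher's exact test), major intrinsic proteins, the aquaporins (6 of 22, 0.0088), nodulin-like proteins (4 of 10, 0.0193), the alpha/beta hydrolase family (6 of 29, 0.0283) and PAP_fibrillin proteins (4 of 13, 0.0468). Of the aquaporins PIP2-1 fell from 646 ± 221 to 84.3 ± 47.9 FPKM and TIP1-1 from 567 ± 184 to 108 ± 46.9 FPKM (mean ± SD, n = 3), and PIP1-1, PIP2-6, PIP2B and TIP2-2 fell by 1.84, 1.81, 1.51 and 2.53 on the log2 scale. Each of these falls is larger than the shift of 0.311 that scaling by library size alone gives to the median gene. Risen genes were enriched in NAC proteins (12 of 47, adjusted p = 8.49e-05), C1 domain proteins (8 of 22, 0.000272), WRKY factors (10 of 39, 0.000388) and C2H2 zinc fingers (5 of 14, 0.0146). Of the WRKY factors WRKY51 rose from 0.672 ± 0.85 to 68.9 ± 15.0 FPKM, and WRKY50 from 3.39 ± 0.625 to 38.5 ± 7.61 FPKM.

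No reads were seen in wild type for 19 genes that reached 1 FPKM in each EsANAC029-OE library, and 1 unnamed locus showed the opposite. Among the 19 were PMEI12, a pectin methylesterase inhibitor (109, 43.7 and 3.78 FPKM in replicates 1, 2 and 3), IAN7, a GTP-binding protein of the AIG1 family (11.4, 2.46 and 2.1 FPKM), and MYB61, a transcription factor (1.06, 1.5 and 1.14 FPKM). Cell division genes went apart between libraries of the overexpressor, with list medians of −1.35, 1.33 and −0.189 in replicates 1, 2 and 3.

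EsANAC029-OE replicate 1 lay apart from replicates 2 and 3, which correlated with each other at 0.942 over tested genes and with it at 0.827 and 0.821. A smooth of gene length and GC content explained 2.58% of the variance of its difference from them, which argues against these as the whole cause. Flower, root and seed markers outside the tested genes summed to 0.32 of the highest sum in the other 5 libraries, but these are near 0 throughout, which excludes nothing; the seed markers summed to 1.33 FPKM against at most 0.611 in wild type and 2.37 in replicate 2, and such tissue stays open. Its difference from replicates 2 and 3 correlated at 0.156 (across genes, which are not independent replicates) with their own difference from wild type. This lies between the bounds set, and the shared term biases it downward, so a stronger form of the same change may or may not be what sets it apart; a different stage or plant, which the labels do not describe, stays untested.

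The fall of photosynthesis genes and the rise of salicylic acid genes were weighed together. Scaling by library size alone moved the median gene to 0.311, small beside the antenna and salicylic acid medians of −2.5 and 3.16. Both medians kept at least 0.853 of their size under it, which followed from values already seen. It shows only that this choice of scale cannot account for medians of this size. After a smooth of length and GC content was removed they kept at least 0.958 of their size, which argues against length and GC content as the whole cause. Another time of day at harvest cannot be told apart from genotype, because harvest times are not in the labels and the clock lists had medians of −0.35 (evening) and −1.20 (morning), which neither oppose each other nor lie near 0. The effect of EsANAC029 stays open as the biological explanation, and so do an infection or a growth tray that differed between the groups, which could not be tested.

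Cold-regulated genes fell although the summed DREB1A, DREB1B and DREB1C transcripts did not. The lowest overexpressor sum of these 3 genes was 1.2 times the highest wild-type sum, which argues against fewer CBF transcripts as the cause at the time of harvest. The highest overexpressor sum of COR15A and COR15B was 0.0948 of the lowest wild-type sum (19.1, 41.4 and 29.2 FPKM in replicates 1, 2 and 3, against 437, 918 and 1376 FPKM), which argues against reads split between the copies. An effect of genotype on a later step and an earlier change in CBF transcripts both stay open, as untested.

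Called genes may lie in local clusters. Among tested genes 152 neighbouring pairs were called in the same direction, against a mean of 54.1 and a highest of 81 in 10000 shuffles (permutation p = 1e-04, the smallest they can give). Without pairs alike in description there were 106 against a mean of 51.7, and among those at least 1 kb apart 58 against 27.5.

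The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. For called genes the real split gave 1359 and the highest other 0 by limma, with at most 653 genes at an unadjusted p under 0.05, so 1 split of 10 was as high. For enriched terms the real split gave 10 and the highest other 0, again 1 split of 10; the other splits had no called genes to test. For lists the real split gave 17 and the highest other 21, and 4 of 10 splits gave as many, the real one included.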
